A study of Mus musculus with 18 samples.

How the data were processed

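RNA from 3 populations of mouse mammary epithelial cells was measured on a pair of Affymetrix expression arrays, MOE430 chip A and chip B, which carry mostly different probe sets. Each population had 3 RNA samples, each RNA sample was hybridised to both chips, and the 18 arrays make 9 arrays per chip. Per the labels' protocols, RNA was prepared with the Arcturus PicoPure method from sorted cells, and the entry for the amplification method is N/A. The labels state biological triplicates for the CFC samples and say nothing on this point for the others. Where replicates are not separate animals or preparations, the p-values measure only the spread between these samples, which may be technical.

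The deposited values are intensities on a linear scale, 1 signal per probe set and array. MAS5 is the only tool named, per the submitters' processing notes; its version and target intensity are not given in the sources used here. Every array of both chips had a mean signal of 1500 after removal of the values below its 2nd and above its 98th percentile, so the authors' scaling was kept and no further scaling was made. Detection calls were not used here. The deposited handling records hold another kind of value (chip type, sample description, fluidics station and scan day), and all 18 records named the RNA sample and the chip of the label. Over the 100 probe sets on both chips, the chip A array of 6 of the 9 RNA samples correlated best with the chip B array of the same RNA sample. Those of CFC3 (r = 0.0551 against 0.166), MYO3 (0.188 against 0.203) and MaSC3 (0.140 against 0.301) correlated better with another sample of their population, so the values do not settle the link between the chips for these. Chip A was scanned on 2 days and chip B on 3 days.

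A pseudocount of 150, which is 10% of the chip's mean signal, was added before taking log2. All log2 fold changes are on this log2(signal + 150) scale, which understates the change of dim genes. A probe set was tested if at least 3 of the 9 arrays of its chip reached a signal of 300. Control probe sets were left out, and the 100 probe sets that both chips carry were tested on chip A only. This left 20160 probe sets on chip A and 21394 on chip B.

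Genes were named from the platform annotation, with symbols updated through Entrez identifiers in a table of the GRCm38.p6 assembly that was used for names only. On chip A, 20380 probe sets had 1 gene symbol, 691 had several and 1555 had none; 20364 symbols were matched through their identifier. On chip B these numbers were 14661, 245, 7605 and 14499. Each gene was represented by 1 probe set, from chip A where possible and then the one with the highest mean log2 signal, which gave 17339 genes (11492 on chip A and 5847 on chip B). Probe sets with several genes or none were counted and not named.

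Tests were made with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with a trend of the variance on the mean signal. One fit per chip over all 9 arrays had a mean for each population and 6 residual degrees of freedom before moderation. The 3 pairwise contrasts and the F test over the 3 populations were adjusted by the Benjamini-Hochberg method within each chip, and a gene was called at an adjusted p under 0.05. The number of arrays limits the precision of every value. The share of probe sets with a signal of at least 300 was 70.0% to 75.6% on the chip A arrays and 76.9% to 80.4% on the chip B arrays.

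There were 26 gene lists, fixed before the data were examined, covering mammary lineages, signalling, metabolism and cell types a sort could carry over. They were tested on the chip A representatives with limma's camera at a preset correlation of 0.01, and adjusted over the 26 lists of a contrast. Camera with an estimated correlation and fry were run beside it. Members on chip B entered the counts and medians only.

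The genes named in the text follow a rule that was also fixed before the data were examined. For each contrast these are the 10 called genes with the largest log2 fold change in each direction whose arrays do not overlap between the groups, and up to 4 called members of each list. Krt5, Krt14, Krt8, Krt18, Acta2, Cd24a and Itga6 are always given. Where fewer than 5 genes were called in a direction, the 5 with the smallest p are named as not called. For genes set apart in MaSC from both other populations, the rule takes the 10 with the largest smaller of the 2 log2 fold changes in each direction. Genes with clone-type names were counted and not named.

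The alternatives were other pseudocounts (1% and 30% of the chip mean) and filters (none, or 50% of the chip mean), quantile normalization, scaling by the probe sets on both chips, eBayes without a trend, array quality weights and fits of only the 2 groups compared. The other alternatives were the replicate number as a block, scan day as a block or random block, each RNA sample left out in turn, another choice of representative, chip A alone and an added threshold of 1 on the absolute log2 fold change. The fits were first tested on simulated data with 200 changed genes in 5 draws. In the simulated MaSC against CFC comparison over 17339 genes, 2.4% of genes changed 2-fold, 20.4% of those changed 4-fold, 48.8% of those changed 8-fold and 63.6% of those changed 16-fold were recovered, with a mean of 2.6 false calls per draw. For the simulated MaSC against MYO comparison over the same 17339 genes the shares were 1.2%, 22.4%, 48.4% and 64.8%, with a mean of 2.4 false calls. Figures were drawn with matplotlib 3.10.9.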

Results

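The series profiled 3 sorted populations of mouse mammary cells, with 3 RNA samples each on 2 array chips. CFC is a fraction enriched for colony forming cells, the progenitors that form colonies in culture, with 1 such cell in every 10 sorted cells per the labels. MaSC is a fraction enriched for mammary stem cells, with 1 stem cell in 50 to 100 cells; both came from freshly dissociated tissue. MYO is a fraction of basal (myoepithelial) cells of about 94% purity, which the labels describe as close to the stem cell fraction in phenotype and poor in stem cells. RNA came from 3000 to 4000 cells for CFC, 2000 to 4000 for MaSC and 3000 to 24000 for MYO. CFC and MaSC were purified by negative magnetic selection and flow sorting, and MYO by immunomagnetic enrichment and flow sorting. The stated aim was to find genes specific to stem cells, with CFC and MYO as the references. Values are given as the mean ± SD of 3 RNA samples, or as a log2 fold change ± SE, with the adjusted p of limma.

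The genes that check the population labels differed as follows. The basal keratin genes Krt5 and Krt14, which encode partner proteins of basal epithelial filaments, had signals of 30718 ± 19579 and 38169.8 ± 4262 in MaSC, 30589 ± 11246 and 40813 ± 24166 in MYO, and 865 ± 597 and 1540 ± 1444 in CFC. Acta2, the smooth muscle actin that marks myoepithelium, had signals of 362819 ± 146950 in MaSC, 424551 ± 78706 in MYO and 11232 ± 6258 in CFC. The luminal keratin genes Krt8 and Krt18 had their highest means in CFC, at 175502 ± 55990 and 133888 ± 60744. Krt8 had a signal of 58075 in MaSC and 35417 in MYO, and Krt18 had 27699 and 14879. Cd24a, a surface glycoprotein gene used in mammary sorting, was highest in CFC at 42766 ± 24880, and Itga6, the integrin alpha 6 gene, was lowest there at 6138 ± 1384.

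**Figure D1:**
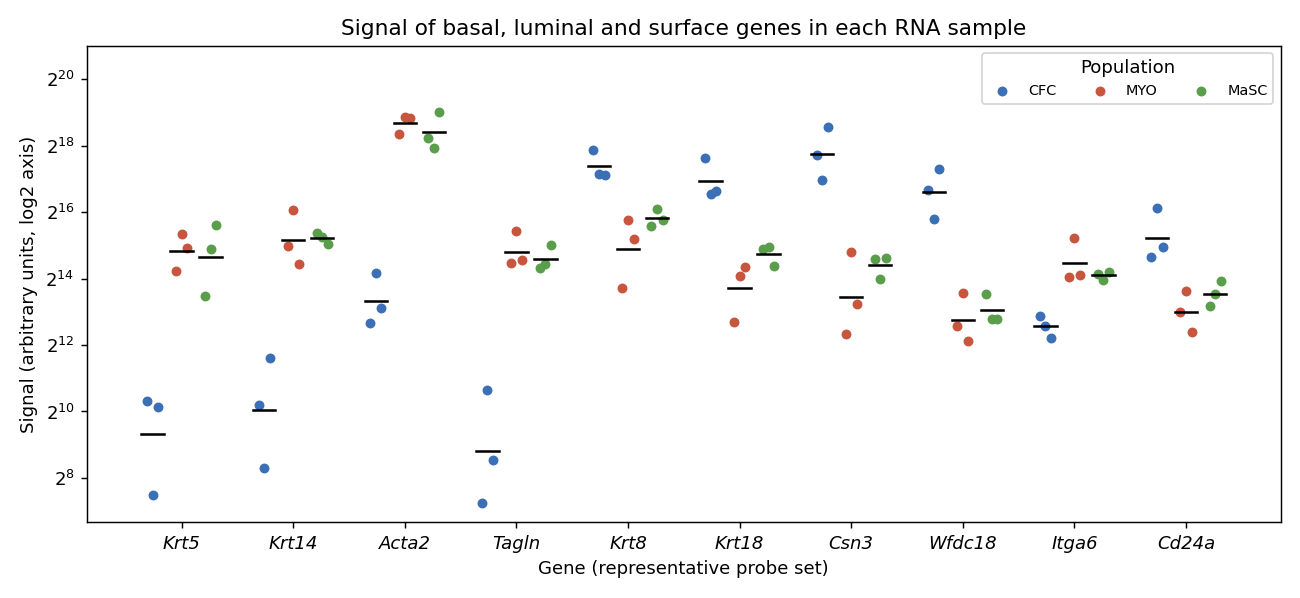
Signal of 10 genes in each of the 9 RNA samples on a log2 axis, with 1 point per RNA sample, colours for the 3 populations and a black line at the geometric mean of each population. Every MaSC and MYO sample lies above every CFC sample for Krt5, Krt14, Acta2, Tagln and Itga6, and every one lies below every CFC sample for Krt8, Krt18, Csn3, Wfdc18 and Cd24a.

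Compared with CFC, the stem cell fraction had higher signals of contractile, basal keratin and matrix genes and lower signals of milk protein and luminal genes. Tagln, which encodes the actin-binding protein transgelin, was 38.2-fold higher (log2 5.26 ± 0.47, adjusted p = 2.51e-08). Acta2 (5.06 ± 0.49), Krt5 (4.95 ± 0.50), Krt14 (4.92 ± 0.49) and Krt17 (4.86 ± 0.46) followed, with Htra1, a secreted serine protease gene, at 4.84 ± 0.43. The smooth muscle myosin gene Myh11 rose by 4.74, the tropomyosin gene Tpm2 by 4.58, the matrix gene Postn (periostin) by 4.47 and Igfbp3, which binds insulin-like growth factors, by 4.29 on the log2 scale. All 3 CFC samples were below the signal of 300 for Igfbp3, and its other probe set, on chip B, gave 1.26 and ended the call (adjusted p = 0.974). In the other direction, Selenbp1, a selenium-binding protein gene, changed by -4.12 ± 0.66, which is 17.4-fold lower (adjusted p = 0.000324). The casein genes Csn1s2a (-3.71), Csn2 (-3.71), Csn3 (-3.33) and Csn1s1 (-3.21), which encode the main milk proteins, fell together with the mucin gene Muc15 (-3.70) and Wfdc18 (-3.52), of the whey acidic protein family. Kcnn4, a calcium-activated potassium channel gene (-3.35), the mitochondrial cristae gene Micos13 (-3.18) and the chemokine receptor gene Cxcr4 (-3.16) completed the 10 largest decreases among called genes whose arrays do not overlap; Hp, with overlapping arrays, changed by -3.19 (adjusted p = 0.0147). Csn1s2a rested much on 1 sample, with -2.34 and an adjusted p of 0.344 without CFC replicate 3. In all, 109 genes were higher and 46 lower in MaSC among 17339 tested. Chip A gave 107 and 46 of these and chip B 2 and 0, although 5847 of the genes tested were on chip B. The no-trend variance model gave 22 and 3, a pseudocount of 1% of the chip mean gave 28 lower calls and no filter gave 30. Lower calls were 27, 21 and 17 without CFC replicates 1, 2 and 3 and 25 without MaSC replicate 2, and higher calls were 66 without MaSC replicate 3.

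The gene lists gave the same comparison group by group. Of 20 measured smooth muscle contractile genes 12 rose (13 adjusted over the list alone), with a median of 2.02. The camera adjusted p was 5.56e-30 with the preset correlation and 0.00245 with an estimated correlation. Of 17 basal keratin and adhesion genes 9 rose (12 adjusted over the list alone; median 1.69), among them Trp63, a transcription factor of basal epithelium, at 3.76 ± 0.53, Snai2 at 2.48 ± 0.63 and Itga6 at 1.52 ± 0.38. Of 22 basement membrane and secreted matrix genes 6 rose (9 adjusted over the list alone; median 1.11), including the collagen-binding glycoprotein gene Sparc (4.16) and the type IV collagen genes Col4a1 (3.48) and Col4a2 (3.47). The Wnt pathway list was called higher (median 0.49, adjusted p = 0.00729), with 1 of 25 members called, the receptor gene Fzd7 (2.22), and 1 adjusted over the list alone. Its adjusted p was 0.0798 with an estimated correlation. Of 19 luminal progenitor and milk protein genes 8 fell (15 lower and 1 higher adjusted over the list alone; median -2.02), and of 22 luminal keratin and junction genes 5 fell (10 adjusted over the list alone; median -1.59), among them Krt19 (-2.57), the claudin gene Cldn4 (-2.22), the membrane protease gene St14 (-2.22) and Krt18 (-2.20). Krt8 changed by -1.56 ± 0.47 and was not called (adjusted p = 0.129). The innate defence list was called lower (median -1.31, camera adjusted p = 3.35e-05, and 0.0122 with an estimated correlation). It had 2 members down, Wfdc18 and the lactoferrin gene Ltf (-2.65), which both also stand in the luminal progenitor and milk protein list. The protease inhibitor gene Slpi (2.29) was the 1 member up. Adjusted over the list alone these counts were 7 lower and 1 higher. Ribosomal protein genes had a median of -0.59 and none of 42 was called alone, before or after adjusting over the list alone; the camera adjusted p of 7.65e-06 became an adjusted p of 0.434 with an estimated correlation.

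Among the lists that were not called between MaSC and CFC, single members still passed the test. Dll1, a Notch ligand gene that stands in both the Notch list (adjusted p = 0.724) and the list of genes proposed as mammary stem cell markers (adjusted p = 0.140), rose by 1.86 ± 0.43. Ltbp2, of the TGF-beta and EMT list (adjusted p = 0.0642), rose by 2.47 and Snai2 was its other called member, the fatty acid desaturase gene Scd1 changed by -2.13 in a fatty acid synthesis list with an adjusted p of 0.316, and Cd24a changed by -1.68 ± 0.41. The sort antigen list, with Itga6 up and Cd24a down, had an adjusted p of 0.353. No call was made for the lists of hormone receptor and response genes (adjusted p = 0.123), cell cycle genes (0.105), immediate early and stress genes (0.146), cholesterol synthesis (0.539), or antigen presentation and interferon genes (0.216). Adjusted over the list alone, 1 stem cell marker, 1 Notch, 3 TGF-beta and EMT and 1 Schwann cell gene were higher, 1 fatty acid and 2 keratinocyte genes were lower, 1 sort antigen was higher and 2 were lower, and the other lists named here had none. The same absence of a call was found for the markers of leukocytes (0.640), endothelium (0.952), fibroblasts (0.114), pericytes (0.539), adipocytes (0.539), erythroid cells (0.458), Schwann cells (0.114) and skin keratinocytes (0.831); the endothelial list had a median of 0.15 and a mean of -0.013. Of the 37 called genes followed through the left-out runs of MaSC against CFC, 15 lost their call without at least 1 RNA sample: Cd24a, Cldn4, Csn1s2a, Cxcr4, Dll1, Itga6, Kcnn4, Krt18, Ltbp2, Ltf, Micos13, Scd1, Slpi, Snai2 and St14. Their highest adjusted p ran from 0.0506 (Krt18) to 0.392 (Cd24a), and 9, 8 and 10 of them lost it without CFC replicates 1, 2 and 3. The no-trend model ended 21 of the 37 calls, those of Csn1s1, Csn2, Csn3, Fzd7, Krt19 and Muc15 included, which held in every left-out run, and each other choice of analysis fixed beforehand, with all samples kept, ended 5 at most.

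In the myoepithelial fraction the same gene groups stood out against CFC. Htra1 was 46.0-fold higher (log2 5.52 ± 0.43, adjusted p = 1.07e-09), followed by Tagln (5.47), Crispld2, a secreted protein gene with an LCCL domain (5.46), Acta2 (5.34) and Krt5 (5.11). Other probe sets, also called, gave 3.99 for Htra1 and 3.26 and 3.77 for Crispld2. Krt14, Tpm2, Myh11, Sparc and Krt17 rose by 4.86, 4.83, 4.67, 4.63 and 4.48. Selenbp1 was lowest against CFC (-4.72 ± 0.66), then Lgals3, which encodes the lectin galectin-3 (-4.51 ± 0.44, adjusted p = 7.16e-08), Fam25c (-4.39), Csn1s2a (-4.27) and Csn3 (-4.26). Ly6d (-4.11), Tph1, which encodes the rate-limiting enzyme of serotonin synthesis (-4.10), the haptoglobin gene Hp (-4.03), Csn2 (-4.01) and Smim22 (-3.84) were also among the 10 largest decreases. In all, 156 genes were higher and 78 lower in MYO. Chip A gave 153 and 76 of these and chip B 3 and 2. The no-trend model gave 53 and 23. Without MYO replicate 2 there were 86 higher calls, and without CFC replicate 2 there were 44 lower calls.

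Of the contractile genes 12 of 20 rose in MYO against CFC (16 adjusted over the list alone; median 2.19), of the basal keratin and adhesion genes 9 of 17 (11 adjusted over the list alone; median 1.88) and of the basement membrane and matrix genes 9 of 22 (14 adjusted over the list alone; median 2.13). Trp63 (4.23), Col4a1 (4.08), Igfbp3 (3.88), Col4a2 (3.68), Snai2 (2.78) and Itga6 (1.88) were among them. With the representative of highest mean on either chip, Igfbp3 gave 1.94 and was not called (adjusted p = 0.931), and Snai2 gave 4.54. Fibroblast markers were called higher, with a median of 0.77 (adjusted p = 0.000275, and an adjusted p of 0.127 with an estimated correlation). Of 16 markers 1 was called, the collagen gene Col3a1 (3.00 ± 0.72), with 3 adjusted over the list alone, and of its MYO arrays that of replicate 3 lay within the range of CFC. Schwann cell markers had a median of 1.06 (camera adjusted p = 0.00178, and 0.0375 with an estimated correlation). Of 6 markers 1 was called, the myelin enzyme gene Cnp at 2.80, with 3 adjusted over the list alone. The list of proposed stem cell markers was higher in MYO (median 0.55, camera adjusted p = 0.00286, and 0.0375 with an estimated correlation). None of its 20 members was called in either count.

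The TGF-beta and EMT list was also higher in MYO (median 0.38, camera adjusted p = 0.00227, and 0.0370 with an estimated correlation). Of 24 members 3 were called, Ltbp2 (2.93), Snai2 and the helix-loop-helix gene Id4 (1.61), and 4 adjusted over the list alone. Other probe sets of Id4 gave 3.03 and 3.08 and passed the threshold. In MaSC against CFC they gave 2.96 and 2.68 and also passed it, while the probe set used did not (1.59, limma adjusted p = 0.0636). The Wnt list (median 0.14, adjusted p = 0.0365) held Fzd7 (2.65) as its 1 called gene, with 3 adjusted over the list alone, and the immediate early and stress list (median 0.39, adjusted p = 0.00247) held Egr2 (2.21), in both counts. These became an adjusted p of 0.127 and an adjusted p of 0.493 with an estimated correlation. Luminal progenitor and milk protein genes were lower (8 of 19 fell, 14 lower and 1 higher adjusted over the list alone; median -1.94), as were luminal keratin and junction genes (8 of 22, and 13 adjusted over the list alone; median -1.67), including Krt19 (-3.61), Krt7 (-3.24), Krt18 (-3.22), Cldn3 (-2.78), Krt8 (-2.48) and Epcam (-1.92). The innate defence list was lower (median -1.62, camera adjusted p = 1.21e-08, and 0.00324 with an estimated correlation). It had 5 members down and 1 up (10 and 1 adjusted over the list alone). Examples are Ltf (-3.33), Cd14, a receptor for bacterial lipopolysaccharide (-3.20), and Wfdc2 (-2.34, but -1.51 with an adjusted p of 0.348 without MYO replicate 2). Ltf, Cd14 and Wfdc18, which was also called lower (-3.80), stand in the luminal progenitor and milk protein list as well. Hormone receptor and response genes were lower (median -0.51, adjusted p = 0.00239), with Foxa1, a partner of the oestrogen receptor (-2.34), and Ptn (-2.10, but -1.03 with an adjusted p of 0.498 without MYO replicate 3) called in both counts, but the list had an adjusted p of 0.0505 with an estimated correlation. Antigen presentation and interferon genes had a median of -0.37 (adjusted p = 0.0290, and an adjusted p of 0.420 with an estimated correlation), and ribosomal protein genes a median of -0.32 (adjusted p = 0.00804, and an adjusted p of 0.658 with an estimated correlation). Neither of these lists had a called member, also adjusted over the list alone. Leaving out 1 RNA sample ended the call of the Wnt list (adjusted p = 0.112, 0.133 and 0.157 without CFC replicate 1, MYO replicate 1 and MYO replicate 2), the immediate early list (0.0934 without CFC replicate 3, 0.802 without MYO replicate 2), the antigen presentation list (0.258, 0.405 and 0.123 without CFC replicate 2, MYO replicate 1 and MYO replicate 3) and the ribosomal list (0.154 without CFC replicate 1, 0.738 without MYO replicate 3). With all samples kept, the filter at 50% of the chip mean, the no-trend model and scan day as a block ended the call of the Wnt list (0.0651, 0.0513 and 0.0732), that filter and array quality weights that of the antigen presentation list (0.0618 and 0.0629), and scan day as a block that of the immediate early list (0.0591).

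No call was made in MYO against CFC for sort antigens (adjusted p = 0.576), the Notch pathway (0.463), cell cycle genes (0.535), cholesterol synthesis (0.618) or fatty acid synthesis (0.229). Hmgcs1, an enzyme gene of the sterol pathway, rose by 1.96, and Scd1 (-2.49) and Lpin1 (-2.65), both of lipid synthesis, fell. Markers of leukocytes (0.535), endothelium (0.849), pericytes (0.536), adipocytes (0.869), erythroid cells (0.576) and skin keratinocytes (0.995) were not called, with 1 keratinocyte gene, Dmkn, called at -2.63. Adjusted over the list alone, 1 cholesterol gene was higher, 2 fatty acid and 2 keratinocyte genes were lower, 1 sort antigen was higher and 2 were lower, and the other uncalled lists had none. Medians and means differed in sign over the chip A members for the cholesterol list (-0.13 and 0.107) and the adipocyte list (0.060 and -0.080). Cd24a was lower in MYO by 4.62-fold (-2.21 ± 0.41). Of the 49 called genes followed through the left-out runs of MYO against CFC, 18 lost their call without at least 1 RNA sample: Cnp, Col3a1, Csn1s2a, Dmkn, Egr2, Epcam, Foxa1, Hmgcs1, Id4, Itga6, Krt7, Krt8, Lpin1, Ltbp2, Ly6d, Ptn, Snai2 and Wfdc2. Their highest adjusted p ran from 0.0505 (Ltbp2) to 0.547 (Foxa1), and 11 and 10 of them lost it without MYO replicates 1 and 2. The no-trend model ended 23 of the 49 calls, those of Cd14, Cd24a, Csn2, Fam25c, Scd1 and Smim22 included, which held in every left-out run, and each other choice of analysis fixed beforehand, with all samples kept, ended 6 at most.

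Between the stem cell fraction and the myoepithelial fraction, limma called 0 genes in either direction. At an unadjusted p under 0.05 there were 668 of 17339 genes (3.85%), below the share of 0.05 expected without any difference. The lowest adjusted p was that of Lgals3 (0.394), at 2.24 ± 0.44 higher in MaSC, with a signal of 7484 in MaSC, 1693 in MYO and 36254 in CFC. The next smallest p in that direction belonged to Fam25c (2.87), Abcf2 (2.81, with all 3 MYO samples below the signal of 300), Galnt1 (2.15) and Renbp (2.13), and in the other direction to Bdnf, the brain-derived neurotrophic factor gene (-2.43), Serpinb11 (-2.55), Nrep (-2.25), Lrpap1 (-2.45) and Frmpd2 (-2.83); none of these 10 genes was called. Other probe sets gave -0.095 for Bdnf, -0.63 for Nrep, and 0.72, -0.91 and -0.47 for Lrpap1. The basal genes had differences of -0.17 for Krt5 (95% interval -1.20 to 0.86), 0.058 for Krt14 (-0.95 to 1.06), -0.28 for Acta2 (-1.28 to 0.72) and -0.36 for Itga6 (-1.14 to 0.42). The sign for Krt14 turned when arrays were scaled by the probe sets on both chips (-0.0116). Krt18 was 1.02 higher in MaSC (0.13 to 1.91, adjusted p = 0.999), Krt8 0.92 (-0.041 to 1.88) and Cd24a 0.53 (-0.32 to 1.37). Lgals3 was called, higher in MaSC, with array quality weights (adjusted p = 0.0138) and without MYO replicate 3 (adjusted p = 0.0139), and in no other setting; over all settings its adjusted p ran from 0.0138 to 1.00. With no gene called in this comparison, 0 genes were set apart in MaSC from both other populations in either direction.

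The basement membrane and matrix list was the 1 list called between MaSC and MYO. Its median was -0.46, with 18 of 22 members lower in MaSC and no member called, also adjusted over the list alone (adjusted p = 0.00668, and an adjusted p of 0.391 with an estimated correlation). Fibroblast markers, at a median of -0.46, were not called (adjusted p = 0.0648, 0.485 with an estimated correlation and 0.740 with fry). Without MYO replicate 2 the matrix list had a camera adjusted p of 0.305, and without MaSC replicate 2 one of 0.184. Over all settings with the preset correlation its camera adjusted p ran from 0.000521 to 0.305. With fry the adjusted p of the matrix list was 0.409. The innate defence list had a median of 0.39 (adjusted p = 0.0783), the luminal keratin list 0.30 (0.109), the milk protein list 0.34 (0.179) and the proposed stem cell marker list -0.38 (0.179). For the basal keratin list the median was -0.054 (0.681) and for the contractile list -0.10 (0.670). The other 18 lists had adjusted p values from 0.0975 for ribosomal protein genes to 0.879 for cholesterol synthesis genes and pericyte markers. Adjusted over the list alone, 1 hormone response gene was higher in MaSC and no member of the other lists differed. Medians and means over the chip A members differed in sign for sort antigens (0.060 and -0.113), leukocyte markers (0.033 and -0.087) and pericyte markers (0.12 and -0.023).

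**Figure D2:**
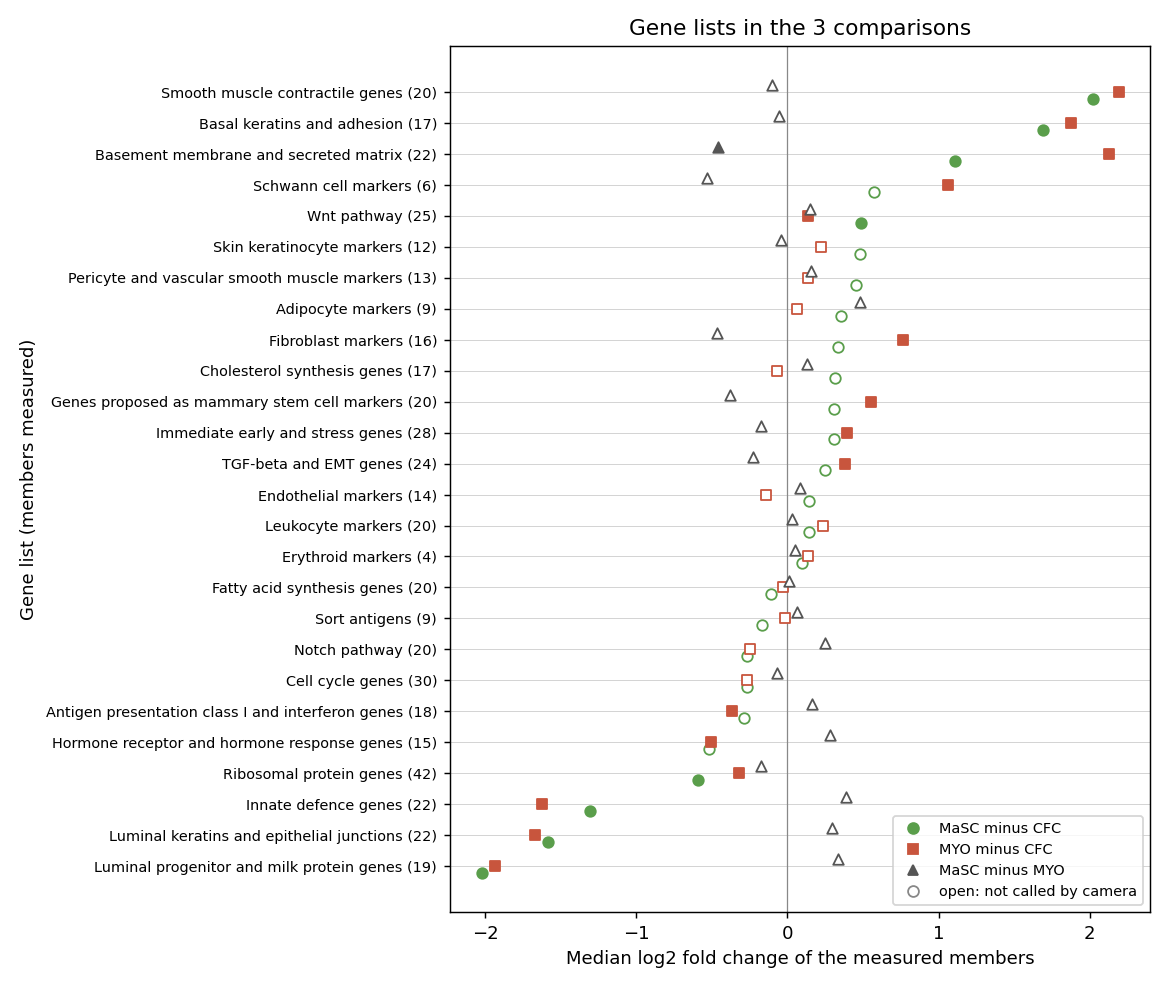
Median log2 fold change of the measured members of each of the 26 gene lists (rows, with the number of members measured) in the 3 comparisons, drawn as circles, squares and triangles; filled symbols are lists called by camera with the preset correlation. Contractile genes (2.02 and 2.19) and milk protein genes (-2.02 and -1.94) mark the ends of the range against CFC, while 1 list, basement membrane and matrix (-0.46), is filled for MaSC minus MYO.

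Over all 3 populations the F test called 215 genes, and 41 with the no-trend model and 132 without CFC replicate 2. Both basal-type fractions differed from CFC in the same genes: 140 genes were called in MaSC against CFC and in MYO against CFC, 104 higher and 36 lower in both. Independent lists of these sizes would share 0.981 and 0.207 genes, but the shared CFC arrays make these lists dependent. In 20 simulated data sets with unchanged groups and shared CFC arrays, at most 0 genes were shared. Such data hardly give calls, with at most 1 per contrast in 5 simulated draws. The value of 0 therefore cannot show how much of the overlap comes from the shared arrays. A further 15 genes were called in MaSC alone and 94 in MYO alone, and all 249 had the same sign in both comparisons. No share in unchanged data was computed for genes chosen by a call, and both comparisons use the same CFC arrays. The difference between the comparisons is the MaSC against MYO test, which called none. Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.632 against 0.498 in unchanged data, with a covariance of 0.407 against 0.245. The same sign was seen for 69.6% of genes against 66.5% in unchanged data. These unchanged data drew the noise of each gene independently. They therefore lack deviations that many genes of a sample share, which could also move these values. The comparison with unchanged data thus does not decide how much the populations share. The 3 CFC samples were too few to divide between the comparisons, which therefore share their controls.

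**Figure D3:**
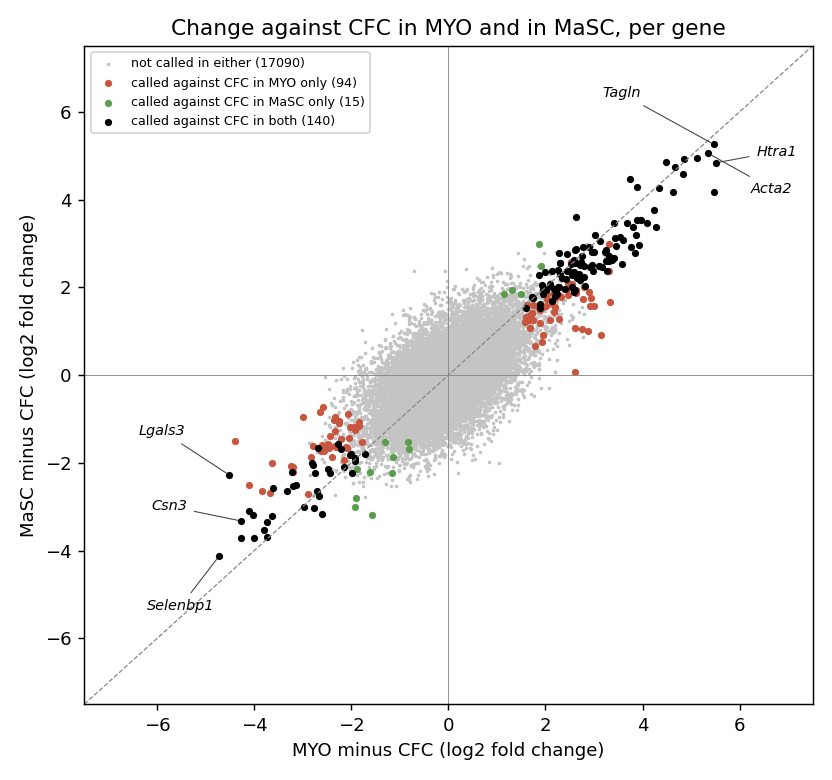
Log2 fold change against CFC of each of the 17339 genes in MYO (x axis) and MaSC (y axis), with the diagonal dashed and colours for genes called in both comparisons (140), MYO alone (94), MaSC alone (15) or neither. All 249 called genes lie in the upper right or lower left quadrant.

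Some measured features of the arrays bear on these comparisons. Fluidics stations were uneven, with all CFC arrays on station 2, MYO and MaSC arrays on stations 1 and 2, and none recorded for MaSC3 on chip B. No alternative took the station into account. Scan days were unevenly spread, with all CFC arrays on the first day. Scan day as a block ended 4 calls of named genes in MaSC against CFC (Dll1, Itga6, Kcnn4 and Snai2). In MYO against CFC it ended 6 (Col3a1, Foxa1, Hmgcs1, Id4, Lpin1 and Wfdc2). With scan day as a block, 77 genes were higher and 48 lower in MaSC against CFC, 115 and 64 in MYO against CFC, 0 between MaSC and MYO, and 152 by the F test; 8, 13 and 1 lists were called in MaSC against CFC, MYO against CFC and MaSC against MYO. On the chip A arrays of the first scan day alone (3 CFC, 2 MYO and 2 MaSC), an alternative chosen after seeing the data, these were 53 and 54, 79 and 68, 0, 148, and 10, 13 and 1 lists, and the matrix list was not called between MaSC and MYO (adjusted p = 0.185). The later days held 1 array at most per population and chip, so they gave no value of their own. The ratio of 3' to 5' beta-actin signal ran from 10.56 to 29.96 on the chip A arrays and from 10.74 to 55.5 on the chip B arrays. Every array thus had more signal at the 3' end, which limits probe sets placed further from it. MaSC replicate 1 had the lowest mean correlation with its own group (0.598 on chip A, 0.426 on chip B), and MYO replicate 1 the highest ratio of 3' to 5' beta-actin signal (29.96 on chip A, 55.5 on chip B). Without both, also chosen after seeing the data, 147 genes were higher and 44 lower in MaSC against CFC, 151 and 71 in MYO against CFC, 0 between MaSC and MYO, and 245 by the F test.

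Several genes have probe sets that disagree with the one used. Among 191 further probe sets of the genes called in MaSC against CFC, 158 had the same sign, 51 were called in the same direction and 0 in the opposite one; in MYO against CFC these numbers were 299, 248, 77 and 0. For 11 of the 37 called genes named for MaSC against CFC and 16 of the 49 named for MYO against CFC, at least 1 further probe set had the opposite sign or under 50% of the log2 fold change of the one used, a limit chosen after seeing the data, and 0 of these probe sets were called. In MaSC against CFC they gave -0.18 and -0.35 for Acta2, -0.18 for Myh11, -0.92 and 1.64 for Trp63, 0.12 for Krt14, whose representative is of a type that can bind related transcripts, 1.19 for Krt17, 0.081 for Sparc, 0.42 for Tpm2, 1.26 for Igfbp3, -0.16 for Csn3, -0.16 for Micos13, and 0.27, 0.13 and -0.68 for Csn1s2a. In MYO against CFC these values were -0.39 and 0.024 for Acta2, -1.11 for Myh11, -0.44 and 1.24 for Trp63, 0.44 for Krt14, 1.42 for Krt17, 0.11 for Sparc, 0.86 and 1.997 for Tpm2, 0.20 for Csn3, and 0.071, -1.69 and -0.93 for Csn1s2a. They were also -0.23 for Cnp, 1.04 for Col3a1, -0.50 for Epcam, 0.20 for Hmgcs1, -1.27 for Lpin1, -0.21 for Ptn and 0.46 for Smim22. The probe sets used for Htra1 and Crispld2 are of the same type as the Krt14 representative. Another Htra1 probe set gave 3.80 in MaSC against CFC. A further Krt14 probe set gave 5.95 in MaSC and 5.62 in MYO against CFC. Which probe sets report the transcript was not tested.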

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

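All tests reported here were chosen before their results were seen, except those on the number of arrays, on the left-out MaSC1 library, on single-array defects, on a mislabelled sample, on the spike-in signal, and on the scan days and chips of the 82-gene split described below. Probe sets that the annotation ties to several genes or to none take no part in the gene comparisons, yet 17 of them were called in MaSC against CFC and 24 in MYO against CFC. Of these, 9 were higher and 8 lower in MaSC, and 15 were higher and 9 lower in MYO. Groups of 3 samples are too small for the test of single outlying samples, which was not applied.

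The grouping of the samples was compared with other groupings. For the F test over the 3 populations, 3 of 100 splits of the 9 RNA samples, the real one included, called as many genes as the real one (215), and the highest of the others called 246. At this share chance can be excluded for the F test only as to the division of CFC from the rest. The 2 splits above the real one (246 and 237), and 1 below it (205), keep the 3 CFC samples together and exchange MYO and MaSC samples. Splits that part the CFC samples called 13 genes at most. For the division of MYO from MaSC chance is not excluded. For pairs of populations 10 splits exist, which is too few for a share under 0.05. In MaSC against CFC 1 split of 10, the real one, called 155 genes and the highest other called 0. In MYO against CFC 1 split of 10, the real one, called 234 and the highest other called 1. In MaSC against MYO the real split called 0 genes, a number that all 10 of 10 splits must reach, so this comparison decides nothing. The highest other split called 82 genes, which points to a structure among these 6 samples that does not follow the populations. That split sets MYO1, MYO2 and MaSC1 against MYO3, MaSC2 and MaSC3, and it is also the split of the chip B arrays into the first scan day and later days. Of its 82 genes, however, 81 were on chip A, whose scan days it does not follow, and 1 was on chip B. With scan day as a block, 0 genes were called between MaSC and MYO.

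No gene was called between MaSC and MYO by limma, with 668 of 17339 at an unadjusted p under 0.05. Too few arrays for any call at all is excluded, since 234 genes were called between MYO and CFC with 3 against 3 arrays in the same fit. Those calls had a median absolute log2 fold change of 2.62, so too few arrays for smaller differences is not excluded. Without MaSC1, 0 genes were called between MaSC and MYO, while the MaSC against CFC count went from 155 to 174. The genes at an unadjusted p under 0.05 between MaSC and MYO went from 668 to 891. A share of 0.05 is expected without any difference, and 668 genes are a share of 3.85%. The rise alone is therefore no sign of differences that MaSC1 hid. With fewer MaSC samples left, the 0 calls cannot settle whether MaSC1 alone hides differences. Differences in single genes, large ones included, stay open, because in simulated MaSC against MYO data over 17339 genes 22.4% of 4-fold, 48.4% of 8-fold and 64.8% of 16-fold changes were recovered. The low share of stem cells in the fraction (1 in 50 to 100 cells) is a biological explanation that was not tested.

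MaSC1 stood apart from all other libraries, with the lowest mean correlation with its own group on 2 of 2 chips, which excludes a defect of a single array. A mislabelled sample of the CFC population is excluded, because its mean over the basal keratin list lay -0.22 (log2) from the other MaSC libraries and 1.96 from CFC. Less labelled RNA on the arrays may account for it: MaSC1 had the highest spike-in signal on 2 of 2 chips (363996 on chip A, where the others ranged from 92085 to 259054), and this test was chosen after the values were seen. Its recorded RNA concentration of 534 (unit not given) was not the lowest of the 9.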

How the results depend on the processing

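Each result was recomputed under the alternatives, and 2 of them, the first scan day on chip A and leaving out MaSC1 and MYO1 together, were chosen after seeing the data. Without a trend in eBayes, 22 genes were higher and 3 lower in MaSC against CFC, 53 and 23 in MYO against CFC, and 41 by the F test; of these calls 25 and 75 were also called with the trend. The pseudocount of 1% gave 28 genes lower in MaSC and no filter gave 30, against 46. The first scan day on chip A gave 53 higher in MaSC and 79 higher in MYO against CFC, with 2 MYO and 2 MaSC arrays left. Leaving out 1 RNA sample gave 66 to 135 higher and 17 to 53 lower genes in MaSC against CFC, 86 to 195 and 44 to 106 in MYO against CFC, 132 to 269 by the F test, and 0 to 1 higher and 0 lower in MaSC against MYO. Array quality weights gave 1 gene (Lgals3) between MaSC and MYO. Lists called in MaSC against MYO numbered 1, and 0 with an estimated correlation, 0 with fry, 2 with a pseudocount of 30%, 7 with array weights, 2 with only the 2 groups compared, 3 with the replicate block, 4 without MaSC1 and MYO1, and 0 to 7 without 1 RNA sample. In MYO against CFC 15 lists were called, 9 with an estimated correlation and 11 with fry. In MaSC against CFC 8 were called, 6 and 7 by those tests. The cause of these differences was not tested. Between MaSC and MYO the sign of small uncalled differences turned. Krt5 gave 0.0932 with array weights and 0.12 without MaSC1 and MYO1, and -0.65 to 0.42 without 1 RNA sample (positive without MYO replicate 2 or MaSC replicate 1). Krt14 gave -0.0116 with scaling by the probe sets on both chips, -0.11 with array weights and -0.11 without MaSC1 and MYO1, and -0.30 to 0.51 without 1 RNA sample (negative without MYO replicate 1 or 3 or MaSC replicate 1). Itga6 gave -0.56 to 0.0204 without 1 RNA sample (positive without MYO replicate 2). Called named genes kept their direction in every alternative run. They fell short of the threshold in 103 of 962 recomputations in MaSC against CFC and 117 of 1268 in MYO against CFC; 15 of 37 and 24 of 49 of these genes passed it in every alternative run. With the other choice of representative, 1 further gene called in MYO against CFC had the opposite sign. Lists called in MaSC against CFC kept their call in 184 of 184 recomputations, and those in MYO against CFC in 325 of 345. All of these recomputations used camera with the preset correlation. They therefore do not count the calls that ended with an estimated correlation or with fry. For lists that were not called, the direction given by camera turned in 14, 31 and 25 recomputations (MaSC against CFC, MaSC against MYO, MYO against CFC); that these turns are not counted as reversals was decided after they were seen. Over all populations the replicate numbers gave no clear pairing: 1 of 9 same-number pairs had a correlation of deviations above 0.1, and in 6 of 18 cases the best match had the same number. Between MaSC and MYO the same-number pairs had correlations of 0.118, 0.0767 and 0.0101, and the other pairs -0.110 to 0.0618. A pairing between these populations therefore stays open. With the replicate block 110 genes were higher and 52 lower in MaSC against CFC, 164 and 78 in MYO against CFC, 0 between MaSC and MYO, and 221 by the F test. List tests were not run with scan day as a random block, on chip A alone (the list tests use chip A in any case) or with the added fold threshold, which does not enter them. The F test was not run on pairs of groups. Signal over background limits dim genes, whose changes the pseudocount shrinks.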

Other observations

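The tests on further members of the gene group below, on scan day and on purification were chosen before their results were seen, and the comparisons with RNA concentration and Gapdh signal and the values of single samples were looked at afterwards. The 6 genes below, of the hypoxia response and glucose uptake, were chosen after their values were seen and stand in none of the fixed lists. Slc2a3 and Slc2a1, which encode glucose transporters, were higher by 4.34 ± 0.54 and 3.11 ± 0.41 (log2) in MYO and by 4.26 ± 0.54 and 3.05 ± 0.41 in MaSC, with adjusted p values from 4.56e-06 to 2.22e-05. Egln3, a prolyl hydroxylase of the hypoxia response, was higher by 3.45 in MYO and 2.95 in MaSC, and the adrenomedullin gene Adm by 2.73 and 2.21. P4ha1, which hydroxylates collagen prolines, was higher by 2.53 and 2.54, and Ero1a, an oxidase of the endoplasmic reticulum, by 2.63 and 3.60, all past the threshold. Other probe sets were uncalled for P4ha1 (1.33 in MYO and 0.52 in MaSC), for Egln3 (2.37) and Plod2 (2.12) in MaSC and, except 1 of 3 in MYO, for Slc2a3 (0.26, 1.38 and 3.09 in MYO, and -0.55, 0.51 and 1.97 in MaSC).

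A list of 32 further genes of glycolysis and the hypoxia response, of which 29 were measured, was then written and tested. In MYO against CFC 24 of the 29 had a positive log2 fold change, with a median of 0.70 and 2 called: Plod2, which hydroxylates collagen lysines (2.71), and the stress response gene Ddit4 (2.28). In MaSC against CFC the median was 0.87, with 22 of 29 positive and 2 called, Plod2 (2.17) and the angiogenic factor gene Vegfa (1.94).

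Whether this group as a whole is higher stays open. A chance pick of genes from the top of the list remains possible, since the unseen members had p = 0.114 by camera with an estimated correlation (p = 6.94e-08 with the preset one) in MYO against CFC, and p = 0.133 with it in MaSC against CFC. Scan day stays open: the first-day MYO and MaSC arrays of chip A had a mean 0.54 above CFC, but MaSC1 (0.0877) and MYO1 (0.15) lay below the highest CFC array (0.17), while MaSC2 (0.70) and MYO3 (1.23) lay above it. Purification method stays open for the same reason, with MaSC, purified like CFC by negative selection, 0.67 above CFC on average, MaSC1 (0.0925) below the highest CFC sample (0.14), and MaSC2 (0.75) and MaSC3 (1.16) above it. MYO1 and MaSC1, the 2 samples at the level of CFC, also shared its low Gapdh signal given below. Gapdh is itself a gene of glycolysis, so its signal is not a measure apart from this group. A biological difference between the fractions was not tested apart from scan day and purification.

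The split of the 6 MYO and MaSC samples that called 82 genes is also the split by recorded RNA concentration, whose unit is not given. MYO2, MYO1 and MaSC1 had values of 997, 823 and 534, and MaSC2, MaSC3 and MYO3 had 531, 378 and 301. The control probe set for the 3' end of Gapdh had signals from 111938 to 118779 on the chip A arrays of MYO2, MYO3, MaSC2 and MaSC3 and from 37549 to 50606 on the other 5.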
